A study of Drosophila melanogaster with 13 samples.

How the data were processed

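RNA from pooled testes (80 per sample, males aged 0 to 2 days raised at 25 °C) of 5 genotypes was measured on 13 single-colour Agilent arrays, per the labels: control (4), dany (3), sa (2), aly (2) and topi (2). Total RNA was labelled with Cy3. The labels describe replicates as biological. Sample groups were taken from the labels. According to the file headers, the authors scanned the arrays and extracted signals with Agilent Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09), on a design annotated to an earlier genome build than the gene table used here, so no positions are given. The deposited scanner files hold linear intensity per spot: a processed signal (background subtracted and detrended within each array, with no scaling between arrays), raw median signal and local background, and other columns of 0 or 1 flags for quality and for standing well above background. The deposited series table holds log2 values whose distributions are nearly identical across arrays (medians 7.89 to 7.90), as after quantile normalization. They correlated with the raw median signal of the same array at a Spearman coefficient of 0.989 to 0.999. Which background correction the authors used for it is not stated, so it served only as an alternative.

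Each array had 45019 spots, of which 1417 were control spots. Spots of the same probe were averaged, leaving out spots with outlier flags where others remained, which gave 32162 probes for 25782 targets. Log2 processed signal minus the 75th percentile of the array was used as the level. A probe was kept if it stood well above background on every array of at least 1 group, and the brightest kept probe represented a target, leaving 19758 targets. No spot was saturated, and 51 to 113 spots per array had an outlier flag. The number of arrays limits the precision: the median standard error was 0.306 for dany and 0.347 for the other mutants against control. Symbols came from a table of RefSeq accessions and synonyms, which matched 549 probes (393 by accession, 156 by clone or transcript synonym) of 468 genes, while 3 probes matched several genes and 31610 none. The array names 15676 FlyBase transcripts that the table does not hold. The probes of dany, sa, aly and topi could not be identified, so the mutated genes could not be checked in their own samples. A matched probe may lie outside the coding part of a gene, and levels of different probes were not compared.

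A linear model with 1 mean per group was fitted to all 13 arrays with limma 3.58.1 (R 4.3.3; 8 residual and 2.42 prior degrees of freedom), so that all groups shared an estimate of the spread. Contrasts were each mutant against control, dany against the mean of sa, aly and topi, sa against the mean of aly and topi, and aly against topi. A target was called changed at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold change, tested two-sided. A target below background on every array of 1 group got an "at least" fold against that group's level, raised where needed to the lowest level that stood above background on each array. Where no raising was needed, it equals the fitted fold. It depends on the background correction and is no guaranteed minimum: with normexp background correction Art7 in dany changed by only 0.04 on the log2 scale. The bounds given below are such folds. Newly detected targets had no probe above background on any control array, a probe above it on every array of the mutant, and a higher level by the limma test. Gene lists were tested with camera (preset correlation 0.01) against the 361 matched genes. Of 36 lists fixed in advance 13 had a matched gene, and 9 sets (2 lists and 7 chromosome arms) had at least 3 tested genes. Because of this shortage, sets by cDNA library of the clone, read from the clone name prefix, and by RNA class were added after the data were seen, and adjusted over the 9 of them within each comparison.

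Named genes followed a rule fixed before the data were examined, as were the tests, lists and alternatives. Against control these were the 6 largest rises and 6 largest falls above background in both groups, the 4 largest rises and 4 largest falls by at-least fold, and up to 4 members of each list. Between mutants they were the 4 largest rises and falls. Genes whose symbol is a bare annotation number were passed over, which left 175 of the 361. The results of some genes that the rule names are not reported here.

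The arrays lay on 4 slides scanned on 3 days. Slide 1 held control 1, dany 1, sa 1 and aly 1; slide 2 held control 2, aly 2 and topi 1; slide 3 held control 3, dany 2, sa 2 and topi 2; slide 4 held control 4 and dany 3. After group means were removed, arrays of the same slide correlated at a median r of 0.560 and arrays of the same replicate number on other slides at 0.0343. Of the latter 11 pairs, the 5 without topi had a median r of 0.489; 4 of them also shared the scan day of slides 2 and 3, and the pair that did not gave -0.032. All 5 pairs without topi on other slides but of the same day lay between 0.481 and 0.678, so that the replicate number could not be separated from the scan day. In a group of 2 arrays the deviations mirror each other, so that these pairs are not independent. The 0.678 of sa 2 with aly 2 is by construction that of sa 1 with aly 1, which shared slide 1. Slide was fitted as a term in an alternative, with values within slides beside it, and this term also takes up the scan day, since each slide was scanned on 1 day. The first component of the levels held 56.0% of the variance and the second 21.8%.

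Alternatives were median, quantile, ribosomal protein gene and spike-in scaling, normexp background correction of the raw median signal (offset 50; no mean signal is in the files), the deposited table, no filter and a filter for signal above background on all arrays, the mean of a target's probes, an intensity trend in the variance, the replicate number or slide as a term, a fit of the compared groups alone, no fold minimum, an estimated correlation in camera, separate control pairs for comparisons that share controls, and leaving out each array. Relative to the 75th percentile the median change over all targets moved in dany by -0.76 (median), 0.35 (ribosomal protein genes), 0.67 (spike-ins) and -0.30 (normexp) on the log2 scale. In sa it moved by -0.28, -0.52, 0.09 and -0.34, in aly by 0.23, -0.73, -0.18 and -0.45, and in topi by 0.13, -0.71, 0.26 and -0.34. The spike-ins, of which 7 of 10 kinds were lit on every array, were read as a scale only.

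The overlap of comparisons that share controls was set against 100 simulated data sets without change and against the 6 ways to give each comparison its own control pair. Tested on simulated data, changes of 2 on the log2 scale added to 50 targets were called in 64% to 74% and changes of 5 in 94% to 98%, none in the wrong direction, with 2 to 12 false calls among unchanged targets. With 50 changed targets of each size, these data held far fewer changes than the real ones, where 41.8% to 63.4% were called against control. The adjusted p depends on that share, so these rates do not carry over to the real calls. In 4294 targets with several probes, the probes were called in opposite directions for 48 to 105 targets. Intervals in the closing section are 95% bootstrap intervals over targets (1000 draws). Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for reading and plotting.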

Results

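Testes of Drosophila melanogaster males aged 0 to 2 days were compared between 1 control and 4 mutants by 1-colour expression microarray. Control testes (4 arrays) came from males with a deficiency on the right arm of chromosome 2 over a wild-type chromosome. The dany testes (3 arrays) carried the same deficiency over a dany allele, so that control and dany shared a background. Testes mutant for sa, aly or topi (2 arrays each) came from other backgrounds. These 3 are meiotic arrest genes: their loss stops germ cells as mature primary spermatocytes. sa encodes a testis TAF, a testis-specific counterpart of a general transcription factor subunit, and aly and topi encode components of the testis meiotic arrest complex (tMAC). Each array held pooled RNA from 80 testes and was labelled a biological replicate. The share of probes above background was 60.9% to 69.1% in control, 75.3% to 76.5% in dany, 68.8% to 72.6% in sa, 64.5% to 66.5% in aly and 62.4% to 64.5% in topi. Replicates of a group correlated across targets at r = 0.97 to 0.992 in control, 0.962 to 0.98 in dany, 0.968 in sa, 0.972 in aly and 0.917 in topi. The array interrogated 25782 targets (genes, transcripts or cDNA clones), of which 19758 were tested. Only 361 tested targets could be matched to a gene symbol, so the counts below cover mostly unnamed transcripts. Values are log2 signal relative to the 75th percentile of the array, fold changes are on the log2 scale unless a fold is given, and SE is the standard error of the limma estimate.

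The comparison of dany with control asked which testis transcripts differed with the dany allele. Whole testes were pooled, here and in the other mutants, so that levels per cell and the mix of cells could not be told apart. Hsc70-1, which encodes a heat shock cognate chaperone, fell from 1.95 ± 0.311 (SD, n = 4) in control to -2.86 in dany (n = 3), a change of -4.82 (SE 0.327, adjusted p = 6.29e-07). The long noncoding RNA lncRNA:Yu changed by -4.30 (SE 0.762, adjusted p = 0.000694) and Nasp, a histone chaperone gene, by -4.07 (SE 0.509, adjusted p = 5.85e-05). Smaller falls were seen for f-cup, a gene of the late-transcribed cup group (-2.69, adjusted p = 1.05e-06), rin, which encodes a stress granule protein (-2.35, adjusted p = 0.000149), and Trpml, which encodes an endolysosomal cation channel (-1.98, adjusted p = 1.05e-05). The calls of rin and Trpml ended under spike-in scaling (-1.68 and -1.31, adjusted p = 0.0672 and 0.145). The transcription factor gene grh (grainy head) was above background on all 4 control arrays and below it in dany, at least 16.1-fold lower (adjusted p = 1.48e-06).

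In dany, Jon65Aiii, of the Jonah family of digestive serine proteases, rose from -5.67 ± 0.427 (SD, n = 4) to -1.54 ± 0.188 (SD, n = 3), a change of 4.13 (SE 0.284, adjusted p = 6.74e-07). The trypsin gene epsilonTry was below background on every control array and at least 34.3-fold higher in dany (adjusted p = 6.18e-05). Both belong to families of similar sequences, and whether the probes tell the copies apart was not tested. The cuticular protein gene Cpr60D (2.93, SE 0.233, adjusted p = 1.95e-06), Sbp2, which encodes a selenocysteine-insertion factor (2.91, SE 0.513, adjusted p = 0.000668), and the gustatory receptor-like gene Grl40a (2.75, SE 0.281, adjusted p = 1.31e-05) rose by similar amounts. So did tor, the receptor tyrosine kinase gene torso (2.57, adjusted p = 2.63e-05). Sh, the Shaker potassium channel gene, was at least 11.5-fold higher than in control, where it was below background (adjusted p = 7.98e-05). The zinc transporter gene Zip42C.2 was at least 6.17-fold higher (adjusted p = 0.000123) and Art7, which encodes an arginine methyltransferase, at least 3.83-fold higher (adjusted p = 0.00452). With normexp background correction the changes of Sh (0.99), Zip42C.2 (0.49) and Art7 (0.04) no longer passed the 2-fold minimum. The lysozyme gene LysE, named here after its values were seen, rose by 4.66 (adjusted p = 5.21e-07). All genes named as changed in dany kept their direction on each slide that held both groups, though the arrays of these slides had also served for the calls.

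In total 5542 targets were higher and 3085 lower in dany than in control (limma, adjusted p under 0.05 and at least 2-fold), 43.7% of those tested. Rises of at least 8-fold (1945 by fitted value, 1824 with targets below background in control at their bounds) outnumbered falls of that size (520, or 516 at bounds). Among the 361 matched genes 70 were higher and 71 lower. With the slide as a term in the fit 5776 were higher and 3442 lower, and 8422 of the 8627 changed targets were shared. Within slides 1, 3 and 4 the lowest share with the same sign was 99.5% of the targets called higher and 99.9% of those called lower. Here and in the comparisons below, the targets had been called with the same arrays, which favours a kept sign. The balance between rises and falls depended on the scaling: rises made up 64.2% of the changed targets, but 33.5% with median scaling, 51.5% with normexp background correction, 77.4% with ribosomal protein gene scaling and 87.3% with spike-in scaling. No target was called in the opposite direction under any of these. For the 3 scalings this was fixed in advance, since each moved all targets alike by less than the 2-fold minimum. Only normexp background correction could have given such a call.

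**Figure D1:**
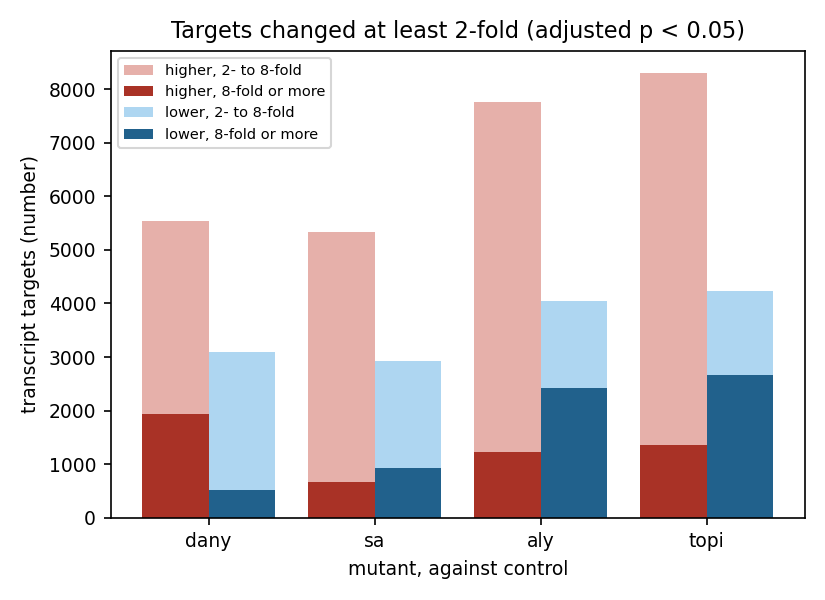
Bars side by side give the number of targets called higher (left) or lower (right) than in control in each mutant, on a linear axis. Each is divided into fitted changes of 2- to 8-fold and of 8-fold or more. dany had the most rises of 8-fold or more (1945) and the fewest falls of that size (520), while topi had the most such falls (2659).

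The fixed gene lists could be followed for few genes, since 23 of the 36 lists had no matched gene. Among the listed comet and cup genes, transcribed after meiosis, soti fell in dany (-1.26, adjusted p = 0.00067), while hale gave -2.32 with a wide error (SE 1.346, adjusted p = 0.169; -2.70 and 2.58e-06 with the slide as a term). The fixed list did not hold f-cup, which fell in all 4 mutants (-2.69 in dany, -2.65 in sa, -1.80 in aly and -1.69 in topi). The soti call ended under spike-in (-0.59, adjusted p = 0.565) and ribosomal protein gene scaling (-0.92). Among ribosomal protein genes, RpS7 was lower (-1.02, adjusted p = 0.00207). RpS7 fell short of the 2-fold minimum without control replicate 3 (-0.92), control replicate 4 (-0.99) or dany replicate 1 (-0.97), with normexp background correction and in the deposited values, and its adjusted p was 0.756 under spike-in and 0.0828 under ribosomal protein gene scaling. The somatic cyst and hub cell markers eya (0.38), puc (-1.06) and ptc (0.64) did not pass (adjusted p = 0.131, 0.226 and 0.261), though puc did with the slide as a term (-1.27, adjusted p = 0.000899). Not called either were wuc, a partner of tMAC (-0.35), the testis proteasome subunit gene Prosbeta4R2 (0.58), the vitelline membrane gene Vm34Ca (0.07), the patterning gene slp1 (-0.05), Cpr49Ag (0.70), the cytochrome P450 genes Cyp9c1 (1.86, adjusted p = 0.0527) and Cyp4d20 (-0.56) and the ionotropic receptor gene Ir7b (-0.64). Cyp9c1 passed without control replicate 1 (adjusted p = 0.0293), whose level stood apart, without dany replicate 2 (0.0212), without either array of sa (0.0498) or of aly (0.0436), and with the slide as a term (1.69, adjusted p = 0.000664). Median scaling called wuc, hale, puc, RpS29, RpL18, Cyp4d20 and Ir7b lower as well. Quantile normalization also called puc, RpS29, Cyp4d20 and Ir7b lower, the deposited values RpS29, and the replicate number as a term hale and Ir7b. Muscle, fat body, blood cell and accessory gland markers had no tested gene. By chromosome arm, 9 of 49 matched genes were higher and 7 lower on the X, 10 and 18 of 65 on 2L, 17 and 11 of 66 on 2R, 17 and 15 of 74 on 3L and 16 and 18 of 94 on 3R. Adjusted over the list alone, the counts were unchanged except on the X, with 8 higher and 6 lower. None of the 9 lists with at least 3 tested genes was shifted (limma camera, smallest adjusted p = 0.962; 0 at an unadjusted p under 0.05; 0 with an estimated correlation). Median, mean and test differed in sign for 3 of the 9.

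Array targets made from cDNA clones were then grouped by the library of the clone, a set chosen after the data were seen. Targets cloned from adult testis were lower in dany as a group: 39 of 114 fell and 10 rose, with a median of -1.10, against 0.26 for the other clone targets (camera over 550 clone targets, adjusted p = 7.56e-06). With an estimated correlation this call was lost (adjusted p = 0.62). The median was -1.29 on slide 1, -1.17 on slide 3 and -1.13 on slide 4, and between -1.86 and -0.43 under the scalings tried. Clones from embryo (40 higher and 15 lower of 141, median 0.41), adult head (55 and 19 of 167, median 0.31) and larva and pupa (10 and 4 of 24, median 0.92) did not pass (adjusted p = 0.136, 0.136 and 0.267).

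In dany testes, transcripts stood above background that no control array showed. Of the tested targets, 2163 were below background on all 4 control arrays. The filter kept these only because a probe stood above background on every array of at least 1 mutant. They are therefore not all targets dark in control, and the share detected in a mutant has no meaning. Among them 1393 were detected on every dany array and passed the limma test, with a median rise of at least 7.06-fold. epsilonTry, Sh, Zip42C.2 and Art7 were among the 21 matched genes of this group. The same count was 692 in sa, 795 in aly and 723 in topi, and 475, 395 and 365 of these were shared with dany. Only dany met the criterion for 699 targets, which does not show that the other mutants differed. In the direct test 906 of the 1393 were higher in dany than in the mean of the 3 arrest mutants and 58 lower. The 1393 had been chosen as high on the dany arrays that this test used, which favours that outcome. With the slide as a term the count in dany was 1385. With normexp background correction it fell to 658, and the dany arrays had the largest share of probes above background.

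Testes mutant for sa, a testis TAF gene, were compared with control. Hsc70-1 fell by 6.51 on the log2 scale (SE 0.371, adjusted p = 8.09e-07), f-cup by 2.65 (SE 0.222, adjusted p = 9.04e-06), Nasp by 2.64 (SE 0.578, adjusted p = 0.00346) and puf, which encodes a ubiquitin-specific protease, by 2.08 (SE 0.208, adjusted p = 2.71e-05). ND-B14.5AL, a paralogue of a mitochondrial complex I subunit gene, changed by -3.56 (SE 1.084, adjusted p = 0.0193) and lncRNA:Yu by -3.18 (SE 0.864, adjusted p = 0.0111). Trpml was at least 7.01-fold lower (adjusted p = 6.26e-06) and grh at least 14.2-fold lower (adjusted p = 1.92e-05). Rises included ND-39, a complex I subunit gene (2.52, SE 0.839, adjusted p = 0.0287), mRpL52, a mitochondrial ribosomal protein gene (2.14, adjusted p = 0.000441), Tim17a2, of mitochondrial protein import (1.83, adjusted p = 9.68e-05), Polr2J, of RNA polymerase II (1.90, adjusted p = 4.91e-05), and the small nucleolar RNA host gene Uhg5 (2.31, adjusted p = 3.55e-05). Cpr60D rose by 2.09 (adjusted p = 0.000118). Below background in control, Sh was at least 7.80-fold higher (adjusted p = 0.000911), the acetylcholine receptor gene nAChRalpha6 at least 7.62-fold (adjusted p = 1.62e-05) and Prosbeta4R2 at least 3.55-fold (adjusted p = 0.00155). Some of these calls ended when 1 array was left out, while the changes kept their sign and passed 2-fold. ND-39 missed the threshold without control replicate 2 (2.34, adjusted p = 0.0615), control replicate 3 (2.03, 0.0596), sa replicate 1 (1.99, 0.181) or sa replicate 2 (3.04, 0.0592). ND-B14.5AL missed it without sa replicate 1 (-3.63, 0.0783) or 2 (-3.49, 0.0937), and lncRNA:Yu without sa replicate 2 (-2.95, 0.0774). The rise of Sh was 3.97 without sa replicate 1 and 2.37 without sa replicate 2. Normexp background correction ended the calls of Sh, nAChRalpha6 and Prosbeta4R2, spike-in scaling those of Polr2J (1.99, adjusted p = 0.0578), Tim17a2 (1.92, 0.0743) and puf (-1.99, 0.0698) with folds about as large, and ribosomal protein gene scaling that of ND-39. The replicate number as a term in the limma fit ended that of ND-B14.5AL (-3.41, adjusted p = 0.0624).

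Of the fixed lists in sa, the ribosomal protein gene RpS29 was lower (-1.28, adjusted p = 0.00134). slp1 rose (1.82, adjusted p = 0.00306). Spike-in scaling ended both calls (-1.18, adjusted p = 0.303, and 1.91, 0.0942) with folds about as large. The comet gene soti (0.26), hale (-1.08), wuc (0.66), eya (0.15), puc (-0.30), ptc (-0.44), Jon65Aiii (0.05), Cpr49Ag (0.71), Cyp4d20 (0.43), Cyp9c1 (-0.03) and Ir7b (1.04) did not pass, but with the slide as a term hale fell (-1.91, adjusted p = 4.28e-05) and RpS3A rose (1.04, adjusted p = 0.0177). Vm34Ca gave 1.32 (adjusted p = 0.121) and passed without control replicate 1 (adjusted p = 0.00849). On the X 14 of 49 matched genes were higher and 3 lower. Adjusted over the list alone, counts differed only on 2L (10 higher and 13 lower in place of 11 and 14) and 2R (10 and 12 in place of 12 and 12). No list was shifted (camera, smallest adjusted p = 0.213 for the X; 1 at an unadjusted p under 0.05; 0 with an estimated correlation), and signs of median, mean and test differed for 4 of 9. Among the clone sets, adult testis targets were lower (52 lower and 13 higher of 114, median -1.64 against 0.70, adjusted p = 1.02e-14; adjusted p = 0.18 with an estimated correlation; slide medians -1.70 and -1.71). Embryo clones were higher (48 and 12 of 141, median 0.76, adjusted p = 0.0372; 0.59 with an estimated correlation), a call that median (0.0584), spike-in (0.0577) and ribosomal protein gene (0.094) scaling ended. In total 5337 targets were higher and 2929 lower in sa, 41.8% of those tested (5832 and 3202 with the slide as a term, 7847 shared). Within slides at least 99.5% of called targets kept their sign. Rises were 64.6% of the changed targets, but 50.6% with median, 40.0% with ribosomal protein gene and 52.8% with normexp processing.

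In testes mutant for aly, a tMAC gene, several transcripts that stood above background on every control array were no longer detected. ND-B14.5AL, at 4.50 ± 0.216 (SD, n = 4) in control, was below background in aly and at least 1969-fold lower (adjusted p = 8.7e-06). lncRNA:Yu was at least 426-fold lower (adjusted p = 4.15e-06), Nasp at least 125-fold (adjusted p = 1.17e-06) and grh at least 9.26-fold (adjusted p = 1.22e-05). Vha100-3, which encodes a subunit of the vacuolar proton pump, changed by -8.09 (SE 1.299, adjusted p = 0.000259) and Hsc70-1 by -5.75 (SE 0.371, adjusted p = 5.96e-07). RpS29 (-2.54, adjusted p = 5.98e-06), sle, of the nucleolus (-2.40, adjusted p = 4.8e-06), and rin (-1.95, adjusted p = 0.000984) fell less. Gen, a Holliday junction nuclease gene, changed by -2.90 (SE 0.667, adjusted p = 0.00282), but by -4.54 without aly replicate 1 and -1.26 without aly replicate 2. Art7 was at least 60.5-fold higher than in control, where it was below background (adjusted p = 7.21e-06), and nAChRalpha6 at least 30.1-fold (adjusted p = 3.1e-07). bic, which encodes the beta subunit of the nascent polypeptide-associated complex, was at least 10.8-fold higher (adjusted p = 1.31e-05) and the receptor gene mthl11 at least 4.87-fold (adjusted p = 0.00156), both lost with normexp background correction. Uhg5 (3.04, SE 0.242, adjusted p = 2.1e-06), Tim17a2 (2.71, SE 0.225, adjusted p = 2.72e-06), mRpL52 (2.70, SE 0.331, adjusted p = 3.73e-05), the translation initiation factor gene eIF3l (2.49, SE 0.186, adjusted p = 1.43e-06) and Sbp2 (2.31, SE 0.582, adjusted p = 0.00486) rose.

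Of the fixed lists in aly, the ribosomal protein genes did not pass as a group (median 1.23, camera adjusted p = 0.848). RpL18 (1.40, adjusted p = 0.00294) and RpS3A (1.23, adjusted p = 0.0392, named after its values were seen) rose while RpS29 fell, and the RpL18 call ended under ribosomal protein gene (0.67, adjusted p = 0.0501) and spike-in scaling (1.22, 0.188). The tMAC partner gene wuc rose (2.23, SE 0.287, adjusted p = 5.29e-05). The 5 matched Y-linked genes were all higher (median 1.96), short of the threshold as a list (camera adjusted p = 0.0849; 0.538 with an estimated correlation; 0.162 with the slide as a term). soti (0.55), hale (-0.38), eya (0.78), ptc (-0.55), puc (0.36), Sh (0.91), Vm34Ca (1.04), slp1 (-0.48), Cpr60D (0.61), Cpr49Ag (1.99), Jon65Aiii (-0.44), Cyp4d20 (0.82), Cyp9c1 (0.30), Ir7b (1.28) and Prosbeta4R2 (0.32) were not called. With the slide as a term hale (-1.14, adjusted p = 0.000202) and Cpr49Ag (1.48, adjusted p = 0.00468) were. Without control replicate 1, Vm34Ca (adjusted p = 0.0125), Cpr49Ag (0.0336) and Ir7b (0.0349) passed. Cpr49Ag also passed without aly replicate 2 (0.0397) and Ir7b without dany replicate 3 (0.0346). On the X 17 of 49 matched genes were higher and 5 lower, or 16 and 4 adjusted over the list alone, which left the other lists' counts as they were. No list was shifted (1 at an unadjusted p under 0.05; 0 with an estimated correlation), and signs differed for 4 of 9.

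Among the sets chosen after the data were seen, adult testis clones were much lower in aly: 79 of 114 fell and 10 rose, with a median of -3.59 (-3.52 with targets below background at their bounds) against 1.17 for other clones (camera adjusted p = 1.86e-27; 0.0307 with an estimated correlation; slide medians -3.52 and -3.79). Antisense RNA genes were lower too (15 lower and 5 higher of 27, median -3.41, or -2.51 at bounds, adjusted p = 0.00121; 0.259 with an estimated correlation). Clones from embryo (79 higher and 14 lower of 141, median 1.26, adjusted p = 0.00121), ovary (26 and 3 of 49, median 1.20, adjusted p = 0.0169) and adult head (87 and 18 of 167, median 1.14, adjusted p = 0.0244) were higher. Those 3 calls were lost with an estimated correlation (adjusted p = 0.259, 0.329 and 0.368), and that for adult head also with normexp background correction (0.0656). In total 7752 targets were higher and 4049 lower, 59.7% of those tested (7983 and 4090 with the slide as a term, 11373 shared). Falls of at least 32-fold numbered 1527 by fitted value and 1460 at bounds, against 135 rises (119 at bounds). Within slides at least 99.7% of called targets kept their sign. Rises were 65.7% of the changed targets, but 44.5% with ribosomal protein gene scaling and 50.8% with spike-in scaling.

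**Figure D2:**
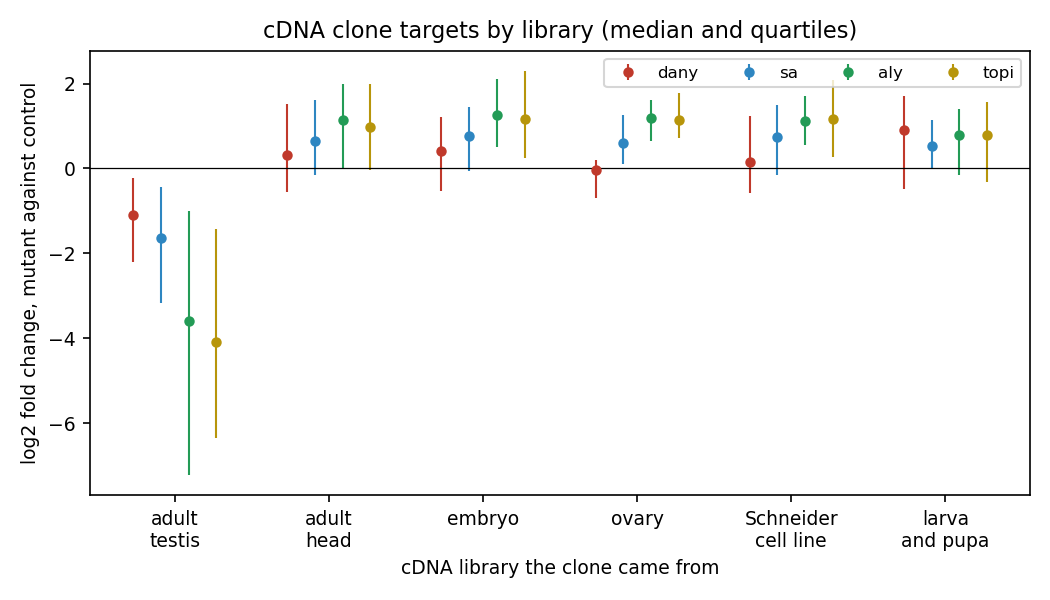
Points are the median log2 fold change against control, with bars from the lower to the upper quartile, of targets grouped by the cDNA library of their clone, for each mutant. The adult testis medians were below 0 in all 4 mutants (-1.10 in dany, -1.64 in sa, -3.59 in aly and -4.09 in topi), as they were under every scaling tried; the other libraries' medians lay between -0.04 and 1.26, and in dany some changed sign with the scaling. Median scaling turned those of adult head (-0.45), embryo (-0.35) and Schneider cell line (-0.61) clones negative. The Schneider cell line median was also negative with quantile normalization (-0.23), in the deposited values (-0.22) and with normexp background correction (-0.40), and the adult head median with normexp (-0.35). The ovary median turned positive under ribosomal protein gene (0.31) and spike-in scaling (0.63).

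Testes mutant for topi, the other tMAC gene, shared many of these changes. ND-B14.5AL changed by -7.05 (SE 1.084, adjusted p = 0.000186), Rtnl2, a reticulon-like gene, by -6.002 (SE 0.615, adjusted p = 1.1e-05) and Hsc70-1 by -5.72 (SE 0.371, adjusted p = 6.78e-07). RpS29 (-2.91, adjusted p = 2.52e-06), the nuclear receptor gene eg (-2.63, adjusted p = 0.00094) and sle (-2.46, adjusted p = 4.09e-06) also fell. Madm, which encodes an adaptor protein, was at least 18.6-fold lower (adjusted p = 1.06e-07), grh at least 8.77-fold, tor at least 6.47-fold and Cpr60D at least 4.46-fold (adjusted p = 2.33e-05, 3.62e-05 and 3.79e-05), the last pair lost with normexp background correction. Art7 was at least 304-fold higher than in control (adjusted p = 1.03e-06), nAChRalpha6 at least 28.9-fold (adjusted p = 3.88e-07) and bic at least 7.49-fold (adjusted p = 3.62e-05), the last under 2-fold with normexp background correction (0.88). wuc (3.05, SE 0.287, adjusted p = 6.21e-06), the ubiquitin ligase gene Hakai (2.68, SE 0.165, adjusted p = 5.06e-07), Sbp2 (2.45, SE 0.582, adjusted p = 0.00324), mRpL9 (2.42, SE 0.256, adjusted p = 1.34e-05) and eIF3l (2.41, SE 0.186, adjusted p = 1.83e-06) rose. LysE, named after its values were seen, rose by 6.33 (adjusted p = 2.76e-07). Cyp4d20 was at least 3.21-fold higher (adjusted p = 0.0174), a call lost without topi replicate 1 (fitted 1.74) or 2 (2.00). It was also lost with the replicate number as a term (1.15, adjusted p = 0.0519), ribosomal protein gene scaling, normexp background correction or the deposited values.

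The 2 topi arrays differed in how far the lost transcripts fell. Without topi replicate 2 the change was -9.84 for ND-B14.5AL, -7.48 for Rtnl2 and -6.45 for Hsc70-1, and without topi replicate 1 it was -4.26, -4.52 and -4.99. Targets at least 32-fold lower on the other aly and topi arrays stood at a median of 5.27% of the control level in topi replicate 2, against 0.24% to 0.41% on the other 3 arrays. The fitted falls in topi are means of these unlike arrays. The count of targets lower in topi was 3976 without topi replicate 2, of which 3922 were among the 4225 called with both arrays.

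**Figure D3:**
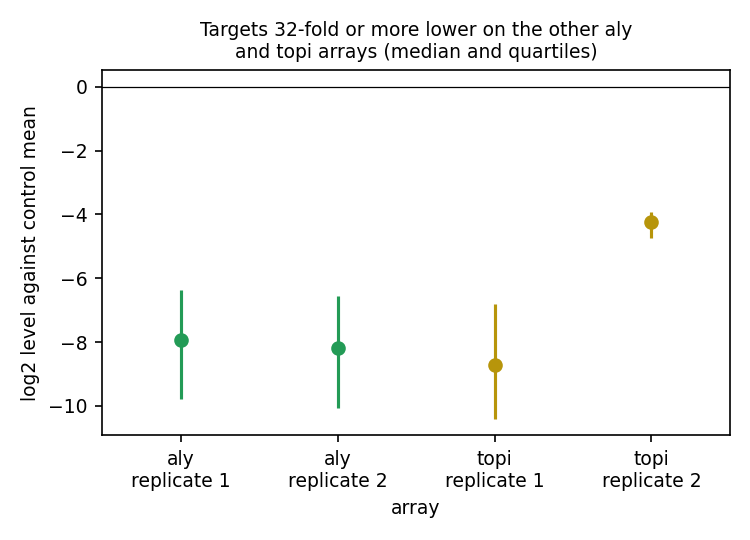
Points are the median log2 level relative to the control mean, with bars from the lower to the upper quartile, of targets at least 32-fold lower than control on the other aly and topi arrays, 1 point per array. topi replicate 2 lay at -4.25 and the other arrays between -8.70 and -7.95.

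Of the fixed lists in topi, the ribosomal protein genes RpS7 (2.22, adjusted p = 1.75e-05) and RpL18 (1.39, adjusted p = 0.0029) rose and RpS29 fell, while the list did not pass as a group (median 1.82, camera adjusted p = 0.491). The RpL18 call ended under ribosomal protein gene (0.68) and spike-in scaling (1.65, adjusted p = 0.056). The cyst cell gene eya rose (1.21, adjusted p = 0.000719), with a call that ended under those scalings (0.51 and 1.47, adjusted p = 0.163 and 0.112), with normexp background correction (0.78) and with the mean of a gene's probes (0.93). Ir7b rose (1.74, adjusted p = 0.0203), a call lost without topi replicate 1 (1.78) or 2 (1.70) and in the deposited values. It was also lost with the replicate number as a term (0.99, adjusted p = 0.0549), spike-in scaling (2.00, 0.0525), ribosomal protein gene scaling (1.03, 0.181) or normexp background correction (0.62). puc (-0.70), soti (-0.48), hale (-2.16), Sh (0.96), Vm34Ca (1.55), slp1 (-0.93), Cpr49Ag (-0.25), Jon65Aiii (-0.31), Cyp9c1 (-0.64) and Prosbeta4R2 (0.58) were not called, and Prosbeta4R2 was negative in the deposited values (-1.23, adjusted p = 0.0112). With the slide as a term hale (-1.07, adjusted p = 0.000275), slp1 (-1.06, adjusted p = 0.00664), Vm34Ca (1.46, adjusted p = 0.0351) and Prosbeta4R2 (1.03, adjusted p = 0.0348) passed. Prosbeta4R2 was below background on every control array, so that its values here are differences from background. Vm34Ca also passed without control replicate 1 (0.00268), and slp1 without control replicate 1 (0.0242) or topi replicate 2 (0.0226). On the X 20 of 49 matched genes were higher and 12 lower. Adjusted over the list alone, counts changed for 3R (35 higher in place of 34) and Vm34Ca (1 higher in place of 0). No list was shifted (camera, smallest adjusted p = 0.491; 0 at an unadjusted p under 0.05; 0 with an estimated correlation), and signs differed for 5 of 9. Adult testis clones, a set chosen after the data were seen, were lower (87 lower and 12 higher of 114, median -4.09 against 1.09, adjusted p = 2.68e-24; 0.0452 with an estimated correlation; slide medians -4.98 and -3.06). Antisense RNA genes were lower (18 lower and 4 higher of 27, median -3.76, adjusted p = 0.00115; 0.285 with an estimated correlation). Clones from embryo (73 and 15 of 141, median 1.17), ovary (26 and 4 of 49, median 1.14) and adult head (77 and 15 of 167, median 0.97) were higher (adjusted p = 0.00446, 0.0105 and 0.0416; 0.285, 0.285 and 0.395 with an estimated correlation). The adult head call ended with the slide as a term (0.0679), under quantile (0.0744) and ribosomal protein gene (0.121) scaling and with normexp background correction (0.0615). In total 8300 targets were higher and 4225 lower in topi, 63.4% of those tested (8518 and 4382 with the slide as a term, 11881 shared), and within slides at least 99.9% kept their sign. Rises were 66.3% of the changed targets, but 47.0% with ribosomal protein gene scaling.

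**Figure D4:**
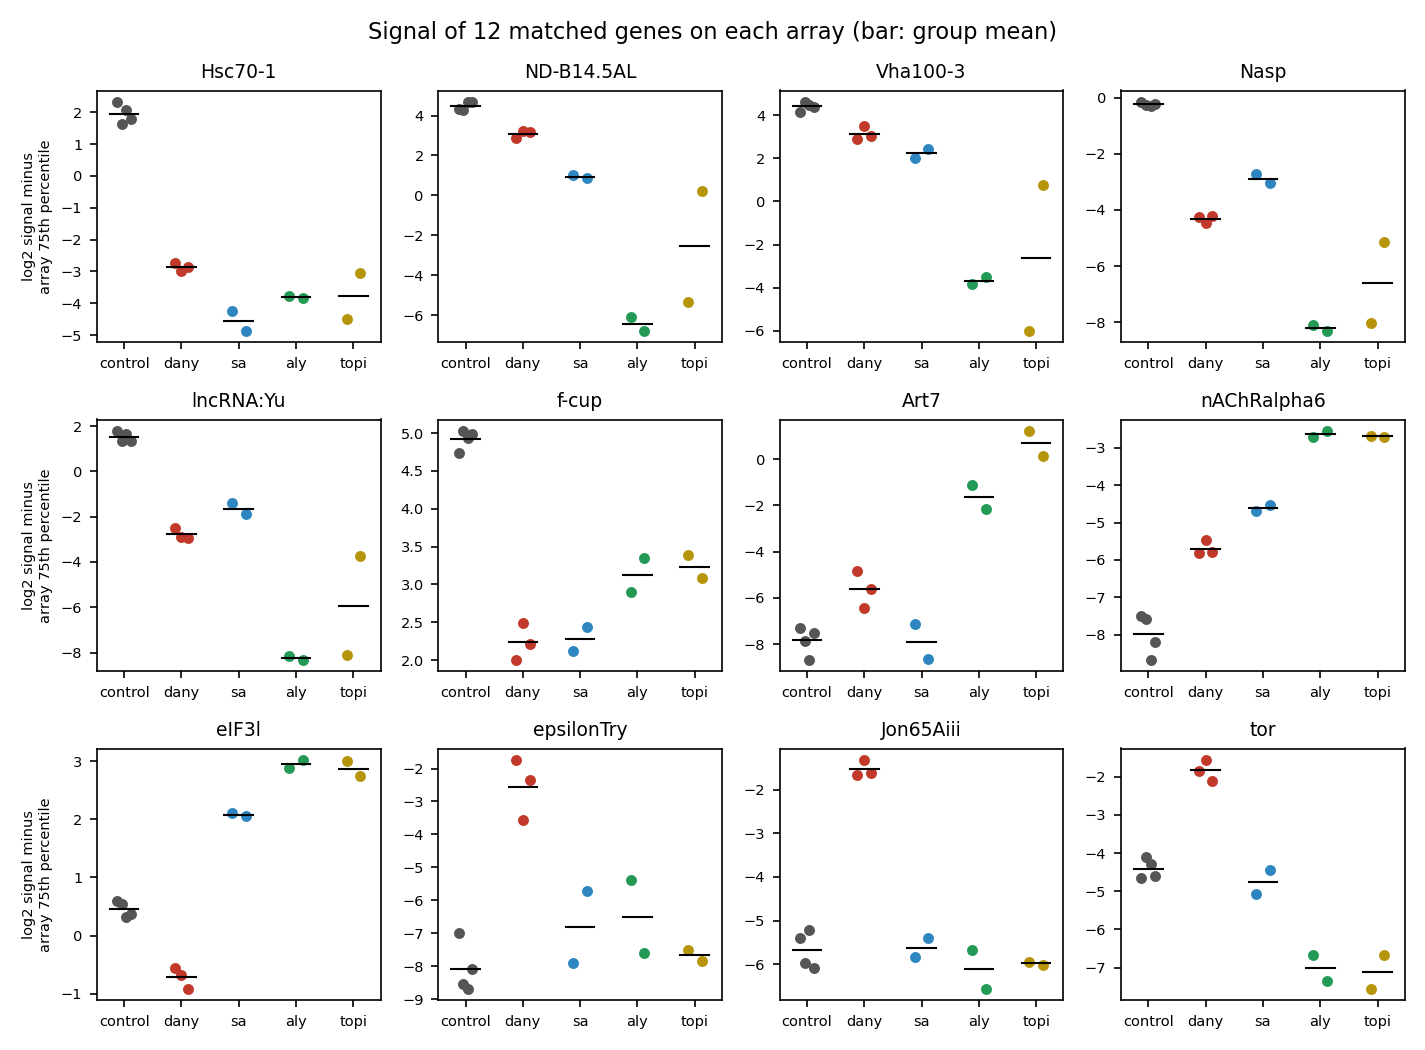
Each panel shows 1 gene: points are the log2 level on single arrays relative to the 75th percentile of the array, and bars the mean of each group (control 4, dany 3, sa, aly and topi 2 arrays). Hsc70-1 was lower in all 4 mutants, ND-B14.5AL was lowest in aly (-6.45), Art7 was highest in topi (0.68), and Jon65Aiii, epsilonTry and tor were highest in dany.

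How far the dany profile overlapped with those of the arrest mutants was measured across targets. Hsc70-1, lncRNA:Yu, Nasp and grh were lower than in control in all 4 mutants; in topi lncRNA:Yu changed by -7.45 (adjusted p = 2.6e-05) and Nasp by -6.35 (adjusted p = 5.04e-06). Of 1999 targets lower in all of sa, aly and topi, 1192 were also lower in dany, 169 were higher and 638 were not called. The medians of the 1999 were -1.75 in dany, -2.74 in sa, -4.44 in aly and -4.34 in topi (-1.75, -2.73, -4.28 and -4.28 at bounds), and 1453 were higher in dany than in the arrest mutants by the direct test. The 1999 had been chosen as low on the arrest mutant arrays used here, which favours deeper medians there and a high count in that test. Without topi replicate 2 the set grew to 2509 targets, and that lower in all 4 mutants from 1192 to 1792 (1152 shared). Of 3606 targets higher in all of sa, aly and topi, 1572 were also higher in dany and 48 lower. The fold changes of dany and the mean arrest mutant correlated across 19758 targets at r = 0.489 (rho = 0.488). Within slide 1, where the arrest mutants were sa and aly only, r was 0.494. Within slide 3, where they were sa and topi replicate 2 only, it was 0.535. Targets are not independent replicates, and the comparisons shared the controls. Simulated groups without any change gave r = 0.508 from the shared controls alone, but a covariance of 0.0894 against the 2.25 observed. With separate control pairs r was 0.45 to 0.489. The covariance above the simulated one was 1.77 for dany and sa, 2.43 for dany and aly, 2.28 for dany and topi, 3.73 for sa and aly, 3.36 for sa and topi and 7.15 for aly and topi. Covariance grows with the size of the fold changes, and r ordered the pairs with dany otherwise. It was 0.539 for dany and sa, 0.427 for dany and aly and 0.4315 for dany and topi, with a simulated r of 0.38 for each. For sa and aly r was 0.734, for sa and topi 0.714 and for aly and topi 0.874. dany and sa shared 1581 lower targets where independent lists of those sizes would share 457.3. aly and topi shared 3451 where 865.8 would be shared. With separate control pairs the mean was 1225 shared against 338.9 for dany and sa, and 3261.8 against 814.8 for aly and topi. Simulation of unchanged groups gave 0 shared targets for each of these. Such groups have hardly any called target to share, so that this simulation decides nothing about the overlap.

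The direct comparison of dany with the mean of the 3 arrest mutants showed where they parted. ND-B14.5AL (fitted difference 5.77, SE 0.885, adjusted p = 0.000176), Vha100-3 (4.50, SE 1.061, adjusted p = 0.00293), tor (4.45, SE 0.267, adjusted p = 2.24e-07) and epsilonTry (4.44, SE 0.644, adjusted p = 0.00012) were higher in dany. ND-B14.5AL stood at 3.09 in dany, 0.94 in sa, -6.45 in aly and -2.55 in topi. bic (-3.45, adjusted p = 7.01e-06), eIF3l (-3.35, SE 0.152, adjusted p = 3.56e-08), the cyclophilin gene Cyp1 (-3.24, adjusted p = 6.05e-06) and the transcription factor gene btd (-2.77, adjusted p = 0.0028) were lower in dany. Some of these genes were below background in 1 or more mutants, so their fitted differences are no bounds. Without topi replicate 2 the difference was 6.70 for ND-B14.5AL and 5.62 for Vha100-3, and without topi replicate 1 it was 4.84 and 3.38. Adult testis clones were higher in dany (67 higher and 15 lower of 114, median 1.91, adjusted p = 1.04e-10; 0.185 with an estimated correlation), with medians of 1.54 on slide 1 (against sa and aly only) and 1.20 on slide 3 (against sa and topi replicate 2 only). So were antisense RNA genes (16 and 5 of 27, median 2.28, adjusted p = 0.0247; 0.441 with an estimated correlation), with 1.32 and 1.18 on these slides, but not under ribosomal protein gene scaling (0.173). Ovary clones were lower in dany (32 lower and 3 higher of 49, median -1.20, adjusted p = 0.000144; 0.185 with an estimated correlation). Embryo clones were lower (52 and 22 of 141, median -0.89, adjusted p = 0.0391; 0.441 with an estimated correlation), but their median turned to 0.11 under ribosomal protein gene scaling (adjusted p = 0.177). In total 5768 targets were higher in dany and 6663 lower (5700 and 6612 with the slide as a term, 11634 shared), with 2614 against 338 at 8-fold or more by fitted value. A set of 3208 targets was higher in dany than in control and than in the arrest mutants, with a median of 3.11 in dany (2.99 at bounds), 0.57 in sa, 0.33 in aly and 0.48 in topi, while 1300 were lower than both. Within slides 1 and 3 at least 99.1% of called targets kept their sign. Targets higher in dany were 46.4% of those changed, but 29.5% with median, 84.0% with ribosomal protein gene and 82.0% with spike-in scaling.

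Between sa and the tMAC mutants, the comparison addressed the testis TAF gene against aly and topi. ND-B14.5AL (5.44, SE 1.084, adjusted p = 0.00237), lncRNA:Yu (5.43, SE 0.864, adjusted p = 0.000645), Vha100-3 (5.38, SE 1.299, adjusted p = 0.00668) and Nasp (4.52, SE 0.578, adjusted p = 0.000174) were higher in sa by fitted difference, and ND-B14.5AL, lncRNA:Yu and Nasp were below background in aly. Art7 (-7.41, SE 0.596, adjusted p = 9.29e-06), LysE (-3.40, adjusted p = 4.43e-05), atos (-3.19, adjusted p = 0.000487) and bic (-2.54, adjusted p = 0.000729) were lower in sa, bic by less than 2-fold with normexp background correction (-0.94). Art7, atos and bic were below background on both sa arrays, so that these differences were taken from background. LysE differed by -0.36 on slide 1, which held aly, and by -5.74 on slide 3, which held topi. Without topi replicate 2 the differences were 6.83 for ND-B14.5AL, 6.53 for lncRNA:Yu, 7.07 for Vha100-3 and 5.24 for Nasp, and without topi replicate 1 they were 4.04, 4.33, 3.70 and 3.79. For Art7 the difference was -8.17 without sa replicate 1 and -6.66 without sa replicate 2. The call of Vha100-3 ended when only these 3 groups were fitted (adjusted p = 0.0738). Adult testis clones were higher in sa (60 higher and 7 lower of 114, median 1.79, adjusted p = 9.85e-12), but less so within slides: the median was 1.49 on slide 1, which held aly, and 0.69 on slide 3, which held topi replicate 2. Antisense RNA genes were higher too (17 and 2 of 27, median 2.20, adjusted p = 0.000171; slide medians 1.96 and 1.48), and embryo clones were lower (34 lower and 11 higher of 141, median -0.53, adjusted p = 0.0112; slide medians -0.55 and -0.43). With an estimated correlation these calls were lost (adjusted p = 0.244, 0.244 and 0.371). In total 3583 targets were higher in sa and 3790 lower (3479 and 3743 with the slide as a term, 6513 shared). Of the 3451 targets lower than control in both aly and topi, 2371 were higher in sa than in those mutants. The 3451 had been chosen as low on the aly and topi arrays that this test used, which favours that count. Within slides 1 and 3 the lowest share that kept its sign was 95.7%. Targets higher in sa were 48.6% of those changed, but 29.9% with median, 59.3% with ribosomal protein gene and 79.4% with spike-in scaling.

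aly and topi, genes of the same complex, gave the fewest changed targets of the 7 comparisons. Madm (6.32, SE 0.261, adjusted p = 1.52e-07), Rtnl2 (5.20, SE 0.71, adjusted p = 0.000619), Uhg5 (4.64, SE 0.279, adjusted p = 2.09e-06) and Cpr60D (2.77, SE 0.305, adjusted p = 0.000154) were higher in aly; Madm and Cpr60D were below background on both topi arrays, so that their values are differences from background. LysE (-5.17, adjusted p = 1.41e-05), Art7 (-2.33, adjusted p = 0.0433), the laminin gene LanA (-2.08, adjusted p = 0.000898) and the kinase-adaptor gene Mob2 (-2.02, adjusted p = 0.00417) were lower in aly than in topi. Rtnl2 differed by 6.68 without topi replicate 2 and 3.72 without topi replicate 1. Art7 missed the threshold without aly replicate 1 (-2.85, adjusted p = 0.0655), aly replicate 2 (-1.81, 0.208) or topi replicate 1 (-1.79, 0.201), and also, with the difference unchanged, without control replicate 2 (0.064), control replicate 4 (0.0583) or dany replicate 3 (0.0643). With only the 4 arrays of these groups fitted, Art7, Rtnl2 (0.0823), LanA (0.0684) and Mob2 (0.0617) missed it, and spike-in scaling ended the calls of Cpr60D (2.33, adjusted p = 0.14), LanA (-2.52, 0.105) and Mob2 (-2.46, 0.116) although their folds stayed above the 2-fold minimum. The Mob2 call also ended with the mean of its probes (-1.05, adjusted p = 0.0768), and that of Art7 without a filter on dim probes (0.0558). None of the clone libraries or RNA classes differed (camera, adjusted p = 0.885 for each). In total 1439 targets were higher and 1514 lower in aly (1805 and 1660 with the slide as a term, 2692 shared), 14.9% of those tested. Slide 2 held both groups, and there all called targets kept their sign, but its arrays had also served for the calls, which favours this. Without topi replicate 2, 2806 targets differed, 2207 of them shared. Targets higher in aly were 48.7% of those changed, but 38.6% with spike-in scaling, 56.8% with median scaling and 64.4% with only these 4 arrays fitted.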

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

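Of the tests below, the comparison of dany arrays with other mutant arrays of the same slide, the digestive gene test and the comparison of targets raised and level in aly were chosen after the results were seen. Control was the only group large enough for a check of single arrays. It covered 65 values, of named genes and of array-wide measures such as the median signal. In 3 of them, all named genes, 1 array lay farther from the rest than Dixon's 95% limit. That is about the 1 in 20 that chance gives. Cyp9c1 stood at -3.18 in control replicate 1 against -4.70 to -4.65 in the others. RpS29 stood at 0.37 in control replicate 3 against -0.18 to -0.10. slp1 stood at -4.58 in control replicate 1 against -3.86 to -3.73.

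topi replicate 2 kept transcripts that topi replicate 1 had lost. Among 1399 targets at least 32-fold lower in topi replicate 1 and aly, it held a median of 4.88% of the control level (quartiles 3.19% to 6.08%). RNA of sa mixed into the sample is argued against, since targets that also fell at least 8-fold in sa stood 1.398 log2 units (95% interval 1.323 to 1.503) above the level it predicts. Control RNA mixed into the sample may account for it: the share was nearly level whether targets had also fallen in sa (4.51%, 617 targets) or not (5.14%, 782 targets), a difference of -0.188 (-0.263 to -0.106) that this explanation required to stay within 1, and it would amount to about 3.9 of 80 testes. Targets at least 8-fold higher in topi replicate 1 and aly stood at a median of -0.31 in topi replicate 2 against replicate 1, where that share would give -0.07. Most of this was not particular to raised targets: chosen without the topi arrays, targets at least 8-fold higher in aly stood at -0.24 (quartiles -0.49 to 0.11) and targets level in aly at -0.26, so that the raised targets decide nothing. A weaker loss in that sample stays open, because the interquartile range of the log2 share, 0.93 (0.826 to 1.008), did not clear the bound of 1 set for it.

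More probes stood above background in dany than in control, on which the 1393 newly detected targets rest. In a first test, without scaling, probes dark in control rose less than probes lit on every array (difference -0.202, interval -0.24 to -0.16), as brighter hybridisation of the dany arrays predicts. By slide the difference was -0.97 on slide 1 and -0.46 on slide 4 but turned to 0.25 on slide 3, so that the test leaned on 2 of the 3 slides. Brightness was judged by the unscaled rise of probes lit on every array. Mutant arrays of the same slide that rose at least as much lit fewer of the 9123 control-dark probes than the dany array. The closest case differed by 658 (1829 in aly replicate 1 against 2487 in dany replicate 1). The dany arrays ranged from 2487 to 2851. By this measure brightness alone is argued against for dany replicates 1 and 2, while replicate 3 had no comparator on its slide. Spike-ins were also dimmer on replicates 1 and 2. Their 75th percentile of signal was higher, though (11.805 and 11.775 against 10.883 to 11.259), so the measures disagree. Unscaled rises over 2-fold covered 37.16% of control-dark probes in dany, but 42.83% in sa, 50.02% in aly and 39.44% in topi. Digestive tract tissue mixed into the dany samples could not be decided: of 4 digestive enzyme genes only 1, alphaTry, stayed below background on every dany array, and Jon65Aiii was above background on all 4 control arrays. A change of transcript levels with the dany allele, the difference the design names, stays open beside it and was not tested separately. In pooled whole testes such a change could not be told from a changed mix of cells.

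The groups of control and dany were set against the other ways to divide their 7 arrays into 4 and 3. For changed targets 1 of 35 divisions, the real one, gave as many as 8627. For newly detected targets 1 of 35, again the real one, gave as many as 1393, where the highest other was 8. A share of 1 in 35 is the lowest that these divisions can give, so that chance is not excluded. The divisions also moved arrays across slides. The targets had been filtered by the real groups, which favours the real division for newly detected targets. The highest other count of changed targets, 4892, came from the division that moves only control replicate 1 and keeps the 3 dany arrays together. For shifted lists all 35 divisions gave 0, as the real one did, so that this comparison decides nothing.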

How the results depend on the processing

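Of the values for single named genes, 4033 kept their side of the threshold under the alternatives, 58 passed it newly, 79 no longer passed and 1 reversed: Prosbeta4R2 in topi was -1.23 in the deposited table (adjusted p = 0.0112) against 0.58. Only values called in the main fit or in the alternative could count as reversed. A value called in neither could change sign and still count among the 4033. This gene was below background on every control array, so that both values are differences from background and the reversal may be noise. Of the counts and correlations, 406 values stayed within the range set for them and 22 moved. The cause was not tested except where the construction shows it. Leaving out 1 array moved none of the counts listed here by over 1.5 times, but without topi replicate 2 the targets lower in all 4 mutants went from 1192 to 1792. The changed targets ranged from 8205 to 9241 in dany, 6386 to 8815 in sa, 10711 to 12247 in aly, 10829 to 12823 in topi and 1985 to 3506 between aly and topi, newly detected targets in dany from 1359 to 1628, and the correlation of dany with the arrest mutants from 0.475 to 0.506. A group left with 1 array was assumed to vary like the others.

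The filter for signal above background on all 13 arrays, which tests fewer targets, left 4568 changed in dany, 4805 in sa, 7103 in aly, 7531 in topi, 7169 between dany and the arrest mutants, 4175 between sa and the tMAC mutants and 1653 between aly and topi, and can give no newly detected target. Spike-in scaling gave 3338 changed in sa, 6846 in aly, 7415 between dany and the arrest mutants, 3084 between sa and the tMAC mutants and 1149 between aly and topi. Fitting only the 4 arrays of aly and topi, with fewer samples, gave 823. Normexp background correction lowered the newly detected targets to 658 in dany, 304 in sa and 478 in aly. Quantile normalization gave 1 shifted list in sa and a correlation of 0.3996. The correlation was 0.4135 in the deposited table, 0.4578 without a filter, 0.5218 with the slide as a term and 0.45 in the lowest of the separate control pairs. The replicate number as a term gave 8793, 8014, 11654 and 12308 changed in dany, sa, aly and topi. Levels of the mutated genes were not run, as no probe could be matched to them. Signal over background limits the folds in both directions: in aly 1955 called targets, rises and falls together, were below background in 1 of the groups. Their folds are "at least" folds, which another background correction can lower.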

Other observations

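Of 61 matched long noncoding RNA genes, 10 rose and 16 fell in dany, 7 and 10 in sa, 21 and 21 in aly and 22 and 25 in topi, and none of the 4 comparisons passed as a set (camera, adjusted p = 0.267, 0.332, 0.61 and 0.323), while lncRNA:Yu was among the largest falls. Antisense RNA genes in dany (6 lower and 2 higher of 27) and sa (10 and 4) did not pass (adjusted p = 0.565 and 0.0985). Clones from the Schneider cell line, an embryo-derived culture, had 15 higher and 6 lower of 55 in dany, 18 and 7 in sa, 26 and 5 in aly and 28 and 8 in topi (adjusted p = 0.565, 0.516, 0.087 and 0.127).

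A small group of targets moved in opposite directions: 169 were higher in dany and lower in all of sa, aly and topi, with medians of 1.88, -2.07, -2.87 and -2.73, and 48 were lower in dany and higher in those 3, with medians of -1.39, 1.68, 2.15 and 2.19. Unmatched transcripts gave the largest changes in dany: FBtr0071871 (7.22, adjusted p = 1.35e-08) and FBtr0083294 (7.01, adjusted p = 8.26e-09) rose, and FBtr0300619 (-9.20, adjusted p = 1.4e-07) and FBtr0082362 (-9.13, adjusted p = 2.52e-06) fell.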
